A study of Plasmodium falciparum K1 with 9 samples.

How the data were processed

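Capped RNA of cultured Plasmodium falciparum K1 was measured in 9 libraries: 1 unfractionated library and 1 library from each of 8 gel fractions. Per the labels' protocols, 100 µg of total RNA from mature parasites entered each capture with a bead-bound form of the parasite's eIF4E. Per the same protocols, 800 ng of captured RNA made the unfractionated library, 7.2 µg was separated on 0.8% agarose, and 100 to 400 ng of each fraction made a strand-specific library for 1 MiSeq flow cell. The reads were handled with TopHat2, Bowtie2 and SAMtools, per the submitters' processing notes, which name no versions. The read counter, the genome build and the annotation are not given in the sources used here, nor are the sizes of the fractions in nucleotides.

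Each deposited file held 5777 lines with a gene or transcript identifier and a number of reads on the sense strand, per the file headers. The deposited values were whole read counts, so although they were recorded under expected counts in the data description, no count was estimated and no rounding was needed. No line named anything other than a gene or transcript, so none was kept out of the totals. At 85 loci the deposited files gave 2 or 3 transcript lines (175 lines) that counted largely the same reads, and the line with the most counts over the libraries was kept. This left 5687 loci, of which 5267 were protein coding. Counts were divided by the total of each library over these loci and given as CPM, counts scaled to a common library total, which were computed here and are not in the deposited counts.

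A table of RefSeq genes for the 3D7 reference strain gave the class of each gene, its genomic span and its neighbours; 5671 of the 5777 lines and 5582 of the 5687 loci matched, and 105 loci did not. The build behind the counts is not known, so no coordinates are printed. The table gave neither coding nor transcript lengths, nor strand or protein products, so genomic span, which includes introns, stood in for coding length. The span was a multiple of 3 for 63.6% of protein-coding genes, so for many of them it may leave out untranslated regions. Gene lists by words of the annotated product (ribosomal proteins and others) were not built for the same reason. The names and roles of genes in the 8 gene lists and the landmark list come from 98 pairs of locus tag and name. These pairs were written from general knowledge before the data were examined, and all 98 locus tags were found in the deposited counts. Genes outside these lists are given by locus tag.

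The main design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Shares of counts by gene list and by class outside the protein-coding genes had exact 95% Clopper-Pearson intervals. Those planned for library totals, detected genes and the shares of protein-coding and of the most abundant genes were not computed. The order of the fractions was tested with an exact two-sided permutation test over all 40320 orders of the 8 fractions, with Benjamini-Hochberg adjustment over the 2 coefficients. The centroid of a gene was its mean fraction number weighted by CPM, for protein-coding genes with at least 100 counts over the 8 fractions, with a counting standard error. Its trend with log10 span was a lowess with a span of 0.3, and a gene was called away from it when the 95% counting interval of its residual lay beyond 1 fraction. A high fraction number means small RNA, so a positive residual means RNA smaller than the trend. Ratios to the unfractionated library used genes with at least 10 counts in the pair and an exact conditional binomial 95% interval, and a gene was called when the whole interval lay beyond 2-fold. With 1 library per group no p-value was given for a gene. The 8 ratios share the unfractionated library, so overlaps between their calls are not reported. Lists were ranked among 10000 random lists of the same size matched on 10 bins of mean log2 CPM. The unfractionated CPM was rebuilt by non-negative least squares from the fractions for genes with at least 10 counts in it. Separated maxima were at least 2 fractions apart, with a valley at or below 0.5 of the lower maximum and a 95% interval of that ratio below 1, in genes with at least 500 counts. Bootstrap intervals used 1000 draws of genes.

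Named genes were the 3 with the highest ratio in each fraction by the interval bound nearest 1 (at least 100 counts there and 10 in the unfractionated library), the 3 members of each list with the most counts, and the 5 highest and 5 lowest residuals. The rule also took the 5 genes with 2 maxima and the 5 in the unfractionated library with the most counts, the 5 farthest from the rebuilt library in each direction (at least 100 counts), and every landmark gene, of which 1 is not reported here by itself. It took 76 genes, 37 with a name; of the 39 without one, a few are given by locus tag and the others are left out of the text. Other list members named in the text (among them RON2, RON3, RON4, RhopH2, MSP5, MSP7, PFK9, LDH, RH1, PMI, HRP2, CENH3, AP2-G, KAHRP, KAHsp40, REX1, REX2 and CLAG9) and PF3D7_1309120, PF3D7_1353000 and PF3D7_0307000 were chosen after their values were seen.

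The alternatives were other scalings (edgeR 4.0.16 TMM, DESeq2 1.42.0 size factors and upper quartiles, used for scaling only), fraction weights from the rebuilt library, other count minimums, thresholds, trends and definitions of position, fractions left out in turn, and libraries thinned to the shallowest. Alternatives added after the data were seen kept every transcript line, used only genes whose span is a multiple of 3, and left out genes with a missing fraction. The ratio calls and the residual calls were tested on simulated counts drawn from the libraries' own profiles and depths, with 200 genes changed. The changed genes had at least 100 counts in the pair for the ratio calls, and at least 500 counts over the fractions for the residual calls. The weights of the rebuilt library, the search for 2 maxima and the list percentiles were tested on simulated data too, and the order test, the correlations and the shares of counts were not. In the simulated comparison of fraction 1 (4292 genes, 50 of them changed by each fold) 82.0% of 3-fold, 96.0% of 4-fold and 100% of 6-fold changes were called, with 1 false call. In fraction 8 (4313 genes) these shares were 84.0%, 92.0% and 98.0%, with 0 false calls. Recovery in genes with fewer counts than the changed ones was not measured. The draws held counting error only, with equal shares in both libraries for unchanged genes, so the false calls do not cover differences between preparations. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3.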

Results

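The series measured the messenger RNA of Plasmodium falciparum K1, a laboratory line of the human malaria parasite. The parasites were grown in red blood cells and harvested mostly as trophozoites and schizonts, the mature stages of the blood cycle. Capped RNA was captured with the parasite's own cap-binding protein, eIF4E, denatured and separated by size on a 0.8% agarose gel. A library was made from each of 8 gel fractions, and 1 more from capped RNA that was not separated, the unfractionated library. Each of these 9 groups held 1 library, so no difference between libraries has a replicate check. The 9 libraries held between 789352 counts, in fraction 7, and 1382127 counts, in fraction 8. The unfractionated library held 1250029 counts, and the other fractions held 1128209 (fraction 1), 1070711 (fraction 2), 1379471 (fraction 3), 1266860 (fraction 4), 1372832 (fraction 5) and 999295 (fraction 6). Between 4573 protein-coding genes, in fraction 7, and 4813, in the unfractionated library, had at least 1 count. Protein-coding genes took between 99.0% and 99.4% of the counts of each library. A count of 0 allowed at most 3 counts, which was 2.40 CPM (counts scaled by the library total) in the unfractionated library and 3.80 CPM in fraction 7. Exact intervals, counting standard errors and floors cover counting error only, and bootstrap intervals cover the draw of genes.

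The first comparison asked how the numbered fractions relate to gene size, since the labels number the fractions without giving a size. Fraction 1 carried the RNA of the longest genes and fractions 7 and 8 that of the shortest. The median genomic span of a gene, weighted by its reads, was 3.231 kb in fraction 1, 2.636 kb in fraction 2, 2.061 kb in fraction 3 and 1.688 kb in fraction 4. It was 1.388 kb in fraction 5, 1.218 kb in fraction 6 and 1.154 kb in both fraction 7 and fraction 8. The unfractionated library, at 1.701 kb, lay between fractions 3 and 4. Across the 8 fractions, fraction number fell with log10 median span, with Pearson's r = -0.967 and Spearman's rho = -0.994. The exact two-sided permutation p was 0.0001 for both, before and after Benjamini-Hochberg adjustment over these 2 coefficients, and is the smallest that these values can give. Without fractions 1 and 8, the 2 farthest from the median fraction number, r was -0.981 (exact permutation p = 0.00278). Without fractions 1 and 2, the 2 whose median span lay farthest from the median of the 8, r was -0.945 (exact permutation p = 0.00556). The 8 fractions come from 1 separation, so the test concerns the order of these libraries and not of repeated gels.

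**Figure D1:**
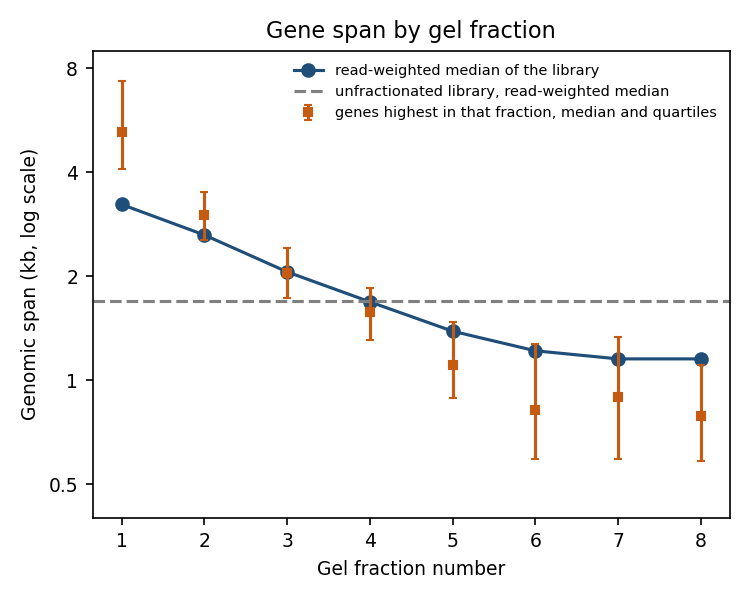
Genomic span in kb (log axis) against gel fraction number. Circles give the read-weighted median of each library, squares with bars the median and quartiles of the genes highest in that fraction, and the dashed line the unfractionated library; the circles fall from 3.231 kb in fraction 1 to 1.154 kb in fractions 7 and 8.

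The second comparison asked how well the position of a gene's RNA in the gel follows the gene's size. Histone H3 RNA (0.411 kb), which encodes a core protein of chromatin, centred on fraction 6.38, and RNA of RPB1 (7.374 kb), the largest subunit of RNA polymerase II, centred on fraction 2.17. This centroid is the mean fraction number weighted by CPM, and it was taken for the 3850 protein-coding genes with at least 100 counts over the fractions. Its median was 4.20, with quartiles of 3.50 and 5.15, and its median counting standard error was 0.0740. Across genes, which are not independent replicates, the centroid fell with span, with Spearman's rho = -0.775 (95% bootstrap interval -0.788 to -0.762) and Pearson's r = -0.737. The median centroid was 5.95 for the 166 genes under 0.5 kb, 4.80 for those of 1 to 1.5 kb and 3.204 for those of 4 to 6 kb. Above 6 kb the medians did not fall further, with values of 3.31 at 6 to 8 kb, 3.34 at 8 to 12 kb and 3.65 for the 56 genes over 12 kb. Fractions 6 to 8 together held a median of 68.1% of the CPM of genes under 0.5 kb, 19.4% at 4 to 6 kb and 27.9% over 12 kb. CPM sets every fraction to the same total, so these are shares of scaled counts and not of the amount of a gene's RNA. Of the 3850 genes, 818 were highest in fraction 1, with a median span of 5.239 kb, and 454 were highest in fraction 8, with a median span of 0.787 kb. Fraction 6 was the highest for 137 genes, fewer than any other fraction.

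**Figure D2:**
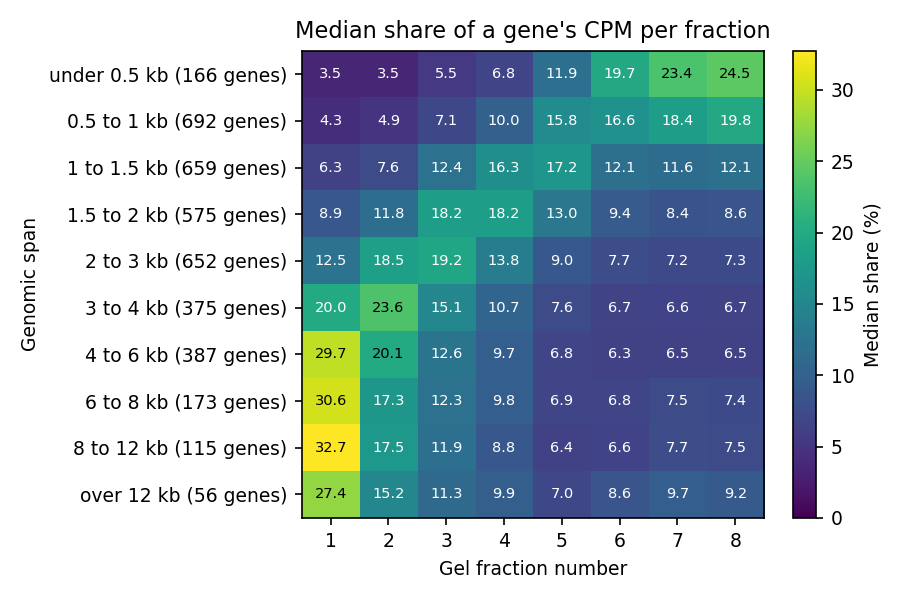
Median share, in percent, of a gene's CPM found in each gel fraction (columns) for genes grouped by genomic span (lines, with the number of genes). The highest share moves from fraction 8 for genes under 0.5 kb to fraction 1 for genes over 4 kb, and fractions 6 to 8 hold more for genes over 12 kb than for genes of 4 to 6 kb.

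Single landmark genes, chosen as well-known RNAs of different sizes, spread over the gel broadly by span, with exceptions. RPB1 had 47.2% of its CPM in fraction 1, and MSP1 (5.163 kb), the main surface protein of the merozoite, 30.1%. MDR1 (4.260 kb), a transporter linked to drug resistance, centred on 3.04 ± 0.08 (counting standard error), the chaperone HSP70-1 (2.034 kb) on 3.53 ± 0.01, and alpha-tubulin (1.901 kb) and beta-tubulin (1.856 kb) on 3.85 ± 0.03 and 3.83 ± 0.02. The vaccine candidate AMA1 (1.869 kb) centred on 4.05 ± 0.04, actin I (ACT1, 1.131 kb) on 4.19 ± 0.01, and eIF4E itself (0.684 kb) on 4.82 ± 0.08. CRT, the chloroquine resistance transporter, centred on 5.00 ± 0.05 although its genomic span, which includes any introns, is 3.096 kb.

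**Figure D3:**
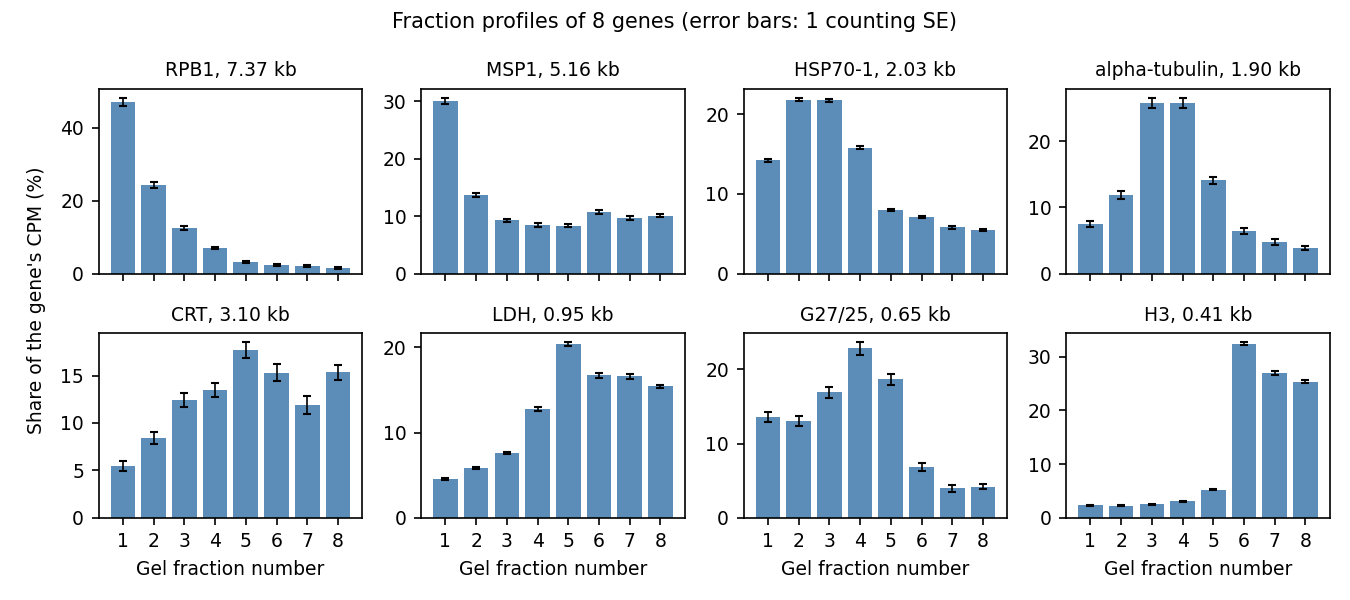
Share, in percent, of each gene's CPM in the 8 gel fractions for 8 genes, with their genomic span in kb; bars show the share and error bars 1 counting standard error. RPB1 has 47.2% of its CPM in fraction 1, whereas CRT, with a centroid of 5.00, and H3, with one of 6.38, lie mainly in later fractions.

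The third comparison set each fraction against the unfractionated library, asking which genes a fraction enriches. Histone RNAs had the highest called ratios of all listed genes in fractions 6 to 8. In fraction 6, H4 was 5.99-fold higher than in the unfractionated library (95% interval 5.60 to 6.41), H2A 4.69-fold (4.38 to 5.03) and H3 4.31-fold (4.15 to 4.48). In fraction 8, H4 was 4.61-fold and H2A 4.23-fold higher, and H3 and H2B (3.19-fold) were called higher too. Fraction 1 was enriched for MESA, a protein exported to the red cell membrane skeleton, at 3.78-fold (3.64 to 3.91), and for RPB1 at 3.07-fold (2.81 to 3.34). The rhoptry neck proteins RON3 at 2.97-fold and RON2 at 2.74-fold, which act in red cell invasion, the glycolytic enzyme PFK9 at 2.78-fold and MSP1 at 2.50-fold were also higher in fraction 1. The glycolytic enzyme LDH, at 0.32-fold, EXP1, a protein of the vacuole membrane around the parasite, at 0.29-fold, and MSP7, a partner of MSP1, at 0.22-fold were lower there. Of the genes without a name here, PF3D7_0802600 was 4.35-fold higher in fraction 1 and PF3D7_1011200 was 8.20-fold higher in fraction 8 (4.88 to 14.7, from 16 counts in the unfractionated library). In fraction 8, RPB1 was at 0.10-fold, alpha-tubulin at 0.24-fold, the endoplasmic reticulum chaperone BiP at 0.24-fold and the merozoite protein MSP9 at 0.21-fold.

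A gene was called when the whole 95% exact conditional binomial interval of its CPM ratio lay beyond 2-fold, which compares 2 libraries and not conditions. In fraction 1, 367 of 4309 genes were higher, with a median span of 5.835 kb, and 625 were lower, with a median span of 0.932 kb. In fraction 2, 44 of 4304 were higher and 425 lower; in fraction 3, 7 of 4369 and 166; in fraction 4, 3 of 4359 and 50; in fraction 5, 7 of 4335 and 220. In fraction 6, 127 of 4259 were higher, with a median span of 0.707 kb, and 430 were lower, with a median span of 3.420 kb. In fraction 7, 221 of 4226 were higher and 491 lower, and in fraction 8, 276 of 4325 were higher (median span 0.694 kb) and 594 lower (2.838 kb). How many genes were higher and how many lower depended on the scaling. With edgeR's TMM in place of library totals every ratio shifted by a log2 amount between -0.22, in fraction 4, and 0.60, in fraction 8. DESeq2's size factors shifted them by -0.07 (fraction 3) to 0.52 (fraction 7), and upper quartiles by -0.03 (fraction 3) to 0.35 (fraction 6). Higher and lower genes with TMM, DESeq2 and upper quartiles, in that order, were 671 and 319, 758 and 244, and 525 and 446 in fraction 1. They were 400 and 144, 399 and 144, and 310 and 202 in fraction 6, and 533 and 195, 526 and 197, and 413 and 271 in fraction 7. In fraction 8 they were 662 and 211, 600 and 252, and 487 and 336. In fraction 2 they were 116 and 329, 90 and 348, and 84 and 363, in fraction 3, 4 and 243, 7 and 188, and 7 and 172, and in fraction 5, 19 and 168, 29 and 155, and 29 and 156. In fraction 4 they were 0 and 111, 3 and 46, and 3 and 50.

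Calls were also counted within the gene lists fixed beforehand. Of the 8 histone genes, 6 were lower in fraction 1, and 4 were higher in fraction 6 and 5 in each of fractions 7 and 8. With the other scalings 5 or 6 were higher in those fractions and 4 to 6 lower in fraction 1. Histones took 1.23% of the counts of the unfractionated library (95% Clopper-Pearson interval 1.21 to 1.25), 0.429% of fraction 1 and 4.09% of fraction 6 (4.05 to 4.13). Of 35 merozoite invasion genes compared, 5 were higher in fraction 1 (MSP1, RhopH2, RON2, RON3 and RON4) and 2 were lower (MSP5 and MSP7), against 7 and 1 with TMM, 8 and 1 with DESeq2 and 6 and 2 with upper quartiles. None was higher and 11 were lower in fraction 8 by library totals, but the balance turned to 4 higher and 2 lower with TMM and 3 and 2 with DESeq2, and was 1 and 6 with upper quartiles. In fraction 7 it turned from 0 higher and 9 lower to 3 and 2 with both TMM and DESeq2, and was 2 and 3 with upper quartiles. Of 4 chaperones, 3 were lower in fraction 8 by library totals and 1 was with each other scaling. Of 11 glycolytic genes, 1 was higher and 3 were lower in fraction 1 (1 and 1 with TMM and DESeq2), and 3 were lower in fraction 8 (1 with TMM and DESeq2, 2 with upper quartiles). Of 8 haemoglobin digestion genes, 2 were lower in fraction 8 (1 with each other scaling) and 2 in fraction 1 (1 with TMM and upper quartiles, 0 with DESeq2). Of 6 genes of the protein export translocon and its vacuole membrane, 2 were lower in fraction 1 (EXP1 and EXP2) and none was called in fraction 8, where TMM and DESeq2 gave 2 higher and upper quartiles 1. Of 13 landmark genes, 2 were higher (RPB1 and MSP1; 3 with each other scaling) and 1 was lower (H3) in fraction 1, and 1 was higher (H3) and 4 were lower in fraction 8 (2 lower with TMM, 3 with the others).

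A list's median centroid was ranked among 10000 random lists of the same size and similar abundance, as a description of these libraries. The 8 histones, with a median centroid of 6.06, lay at percentile 99.9, and the 33 merozoite invasion genes with enough counts, at 3.72, lay at percentile 1.16. The 6 ring-stage exported genes with enough counts, also at 3.72, lay at percentile 14.2 (33.1 for the 4 of them with at least 500 counts, at 4.16, and 19.4 with fractions weighted by the least-squares fit to the unfractionated library), the 4 chaperones, at 3.55, at 7.15, and the 11 glycolytic genes, at 4.34, at 40.1. The haemoglobin digestion genes, at 4.39, lay at percentile 68.0 and the export translocon, at 4.44, at 54.9. After the trend with span was removed, the histones lay at percentile 68.7 with a median residual of 0.27 fractions, and the merozoite genes at 36.1 with 0.05. With a wider lowess span of 0.6 the histones lay at percentile 41.1 with 0.09, and the merozoite genes at 17.3 with -0.04, so the sign of the latter turned. With the main lowess span of 0.3, the ring-stage exported genes lay at percentile 0.45, with a median residual of -0.68 (95% bootstrap interval -1.24 to -0.01). Of these 6 genes 1, HRP2, was called as running larger than its span trend, and the residuals ran from -1.42 for HRP2 to 0.05 for ETRAMP2. With that span the median residual was -0.32 for the chaperones (percentile 5.56), 0.01 for glycolysis (21.6), -0.16 for haemoglobin digestion (19.4) and 0.33 for the export translocon (86.9).

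**Figure D4:**
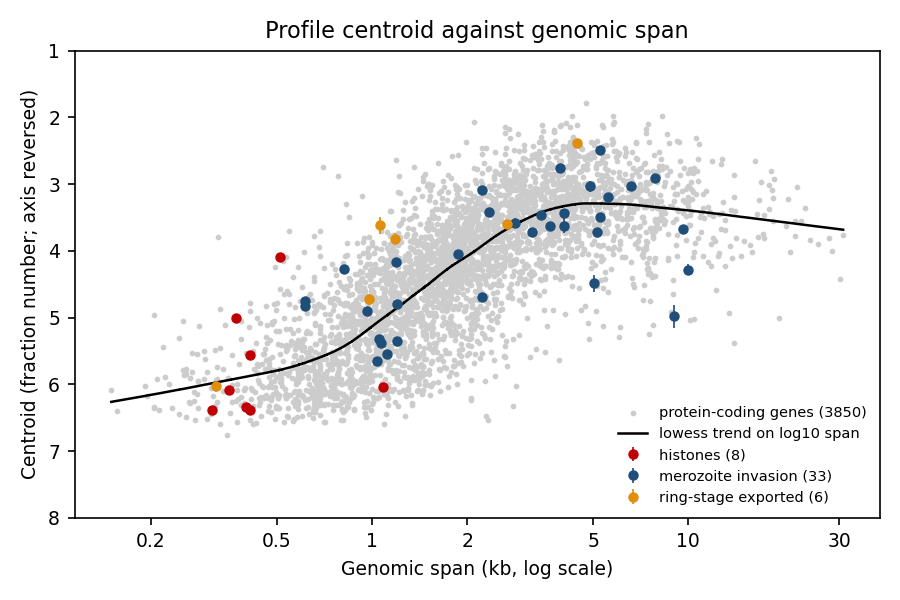
Centroid (mean fraction number weighted by CPM, axis reversed so that larger RNA is at the top) against genomic span in kb (log axis) for 3850 genes in grey, with the lowess trend and 3 gene lists in colour; error bars are 1 counting standard error. The median centroid is 6.06 for histones and 3.72 for merozoite invasion genes, and the trend flattens above 4 kb.

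The next question was which genes ran at another size than their span gave. The RNA of CRT ran smaller than its span trend by 1.49 fractions, and so did that of H2A.Z, a histone variant, by 1.03. RH1, an invasion ligand, was called smaller by 1.61, from 201 counts over the 8 fractions. It had 14.5% of its CPM in fraction 1 and 52.9% in fractions 6 to 8, so its centroid does not stand for a single size. The RNA of PMI (plasmepsin I), a haemoglobin protease, ran larger, with a residual of -1.91, as did that of G27/25, a sexual-stage protein, at -1.86, and CENH3, the centromeric histone, at -1.69. HRP2 (-1.42), a histidine-rich protein exported to the red cell, and MSP2 (-1.15), a merozoite surface protein, also ran larger. RPB1 had a residual of -1.16, but, like RPB1, genes of 6 to 8 kb had their highest median share in fraction 1, at 30.6%. RPB1 held 5.79% of its CPM in fractions 6 to 8, against a median of 22.5% for those genes, so its residual need not mean larger RNA. Among 3850 genes, 194 ran smaller, with a median span of 1.848 kb, and 108 ran larger, with a median span of 1.374 kb. The largest residuals belonged to genes without a name here, 2.70 for PF3D7_1023600 and -2.85 for PF3D7_0731700. The calls rest on counting intervals and a span that includes introns and may leave out untranslated regions. Genes called larger are thus set against a span that may be shorter than their RNA. With fractions weighted to rebuild the unfractionated library the calls numbered 95 and 42. In that weighting the residuals of H2A.Z (0.88), MSP2 (-1.01), RH1 (1.21), HRP2 (-1.08) and RPB1 (-0.84) no longer had an interval beyond 1 fraction. PMI, HRP2 and H2A.Z have close relatives in the genome, and reads shared between copies would make their values uncertain.

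A further question was whether a gene's RNA appeared at more than 1 size. Profiles with 2 separated maxima were found for 54 of 2435 genes with at least 500 counts, and for 5 in simulated profiles with 1 peak and the same depths. The simulated profiles held counting error only, so the 5 do not cover differences between preparations. The earlier maximum was in fraction 1 for 41 of the 54 and the later in fractions 6 to 8 for 49, and 24 of the genes spanned over 6 kb. No gene of the fixed lists was among them. PF3D7_0505700 (2.775 kb) peaked at 411 CPM in fraction 2 and 266 CPM in fraction 7, with 77.1 CPM in fraction 6. The count was 247 with a valley of up to 2/3 of the lower maximum and 233 with a minimum of 100 counts. Maxima were taken in CPM, which sets every fraction to the same total. No other scaling or weighting of the fractions was tried for them, so whether these maxima depend on it was not tested.

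The last comparisons asked whether the fractions together account for the unfractionated library. A weighted sum of the 8 fractions gave the unfractionated values of 4026 genes with an R2 (squared correlation) of 0.980 (95% bootstrap interval 0.978 to 0.981) on the log2(CPM + 1) scale. The weights were fitted to this same library, and equal weights gave an R2 of 0.973. The R2 therefore says little about how completely the fractions account for the library. The glycolytic enzyme GAPDH, the most abundant of the named RNAs at 12215 CPM, had an observed to rebuilt ratio of 1.00, and H3 one of 1.01, whereas H4 had 0.74 and H2B 0.77. Beyond 2-fold lay 22 genes, 12 above the rebuilt value, among them PF3D7_0501400 at 2.06, and 10 below it. With no minimum count 146 genes lay beyond 2-fold, and with at least 50 counts 2 did. The fitted weights were largest for fractions 5 and 3 and 0 for fraction 6. Neighbouring fractions were alike, with Pearson's r across genes of log2(CPM + 1) from 0.962 to 0.981, and fractions 1 and 8 had r = 0.802. The least distinct pair was fractions 7 and 8, with r = 0.981 and a chi-square per degree of freedom of 1.73, against 4.70 for fractions 6 and 7.

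Markers of other stages were read as shares of counts, because the harvest was of mature stages. The 8 gametocyte genes took 0.0397% of the unfractionated library (95% Clopper-Pearson interval 0.0363 to 0.0433), mostly G27/25 (373 counts) and Pfs16 (113 counts). Only these 2 reached 100 counts over the fractions, so their median centroid of 4.72 was not ranked. None of the 2 or 3 with enough counts to compare was higher in any fraction, under any scaling. By library totals Pfs16 was lower in fractions 1 and 2 and G27/25 in fractions 7 and 8, and with each other scaling 1 gene was lower in fraction 2 and none elsewhere. AP2-G, the regulator of sexual commitment, had 0 counts in all 9 libraries, which allows up to 3 counts in each. The ring-stage exported genes took 1.30% of the unfractionated library (1.28 to 1.32) and 3.02% of fraction 1 (2.98 to 3.05), where MESA alone had 13111 counts. In the unfractionated library GBP130 held 12166 and MESA 3848 of the list's 16284 counts. The share therefore rests mostly on these 2 genes and does not measure ring-stage RNA as a whole. KAHRP, KAHsp40, REX1 and REX2, exported proteins of the same list, had 0 counts in all 9 libraries. Of the ring-stage genes compared, 1 was higher in fraction 1 (2 with each other scaling) and 2 were lower in fraction 8 (1 higher and 1 lower with each other scaling). Merozoite invasion genes, the schizont markers, took 4.30% (4.26 to 4.33) of the unfractionated library and 6.77% of fraction 2, and haemoglobin digestion genes, the trophozoite markers, took 0.190%. Ribosomal RNA, which is uncapped, had 30 counts in the unfractionated library and at most 38 in a fraction, in fraction 6. Mitochondrial genes had 10 counts in the unfractionated library and at most 20 in a fraction, and apicoplast genes had 1 count over the 9 libraries.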

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

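The tests of introns and of neighbouring genes without reads were chosen after the results were seen; the tests of carry-over, breakage, loss and neighbouring RNA were written before their results were seen.

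Transcripts outside the protein-coding genes took a larger share of counts in some fractions than in the unfractionated library, the only control, and no comparison of the report uses them. Small nucleolar RNA took 0.620% of fraction 6 (95% Clopper-Pearson interval 0.605 to 0.636) against 0.353% of the unfractionated library, with PF3D7_0307000 the most abundant at 1995 counts. Small nuclear RNA took 0.00881% of fraction 6 (88 counts) against 0.00256% (32 counts). Other non-coding RNA took 0.135% of fraction 8 (0.129 to 0.141) against 0.0710%, and 1507 of its 1866 counts belonged to PF3D7_1309120. Loci without an annotated class took 0.0492% of fraction 8 against 0.0294%. Pseudogenes took 0.384% of fraction 1 (0.373 to 0.396) against 0.243%, and 2498 of their 4333 counts belonged to PF3D7_1353000.

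RNA of genes over 4 kb in fractions 6 to 8 was the first of 3 patterns weighed, and the design gives no biological group that could be set against the technical explanations. The values argue against a constant carry-over of unfractionated RNA as the whole cause. The summed CPM of fractions 6 to 8 over the unfractionated CPM rose with span across 747 genes over 4 kb (Spearman's rho = 0.226, 95% bootstrap interval 0.158 to 0.292). For loss of long RNA, the observed over rebuilt unfractionated CPM of 171 genes over 8 kb was 0.952 times that of all genes (0.927 to 0.978), where a loss would raise it. This argues only against a loss during the separation greater than that of other RNA in the same fractions. A loss shared by all RNA of fraction 1 would be absorbed by that fraction's weight. A loss before the captured RNA was divided would lower both sides and could not show. Breakage of long capped RNA stays open as a hypothesis and may contribute. The same ratio of summed CPM had a median of 1.95 over 8 kb and 1.47 at 4 to 6 kb, 1.33 times as high (1.19 to 1.47). Because the CPM of several libraries is summed, a value above 1 does not mean enrichment over the unfractionated library. Carry-over and breakage were judged from the same rise with span, which the shares by span class also show. Breakage therefore has no separate support here.

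Genes away from the span trend were the second pattern, again with no biological explanation tested. For genes with smaller RNA, introns counted in the span may contribute, since 42.3% of the 194 genes had a span that is a multiple of 3 against 65.1% of the genes not away from the trend, a ratio of 0.650 (0.550 to 0.767). With only spans that are multiples of 3 and the trend fitted again, 114 of 2473 genes still ran smaller, against 194 of 3850 with all spans. A span with introns can also be a multiple of 3, so such genes can remain in this set. How much of the pattern introns explain therefore stays open. For most genes with larger RNA, the values argue against reads of a longer RNA of a neighbouring gene. Of the 108 genes, 26.9% had a neighbour at or below their own centroid against 24.8% expected. The whole interval (-4.79 to 8.42) of the difference of 2.03 percentage points lay below the 10 points set beforehand. Strand was not in the reference, so neighbours on both strands entered that test, and only those with at least 100 counts over the 8 fractions could count. Both can blur a difference, so this explanation stays open for a smaller part of the genes. Untranslated regions were not tested.

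Neighbouring genes without reads were the third pattern. The 23 genes from PF3D7_0935400 to PF3D7_0937700, which include CLAG9, REX1 and REX2, had 1 count in total over the 9 libraries, and the 18 genes from PF3D7_0200200 to PF3D7_0202100, which include KAHRP and KAHsp40, had 4. Each run ended 1 gene short of its chromosome end, and as many genes at the other 26 chromosome ends had at least 1262 and 414 counts, respectively. Such runs were not limited to these places. With these included, there were 22 runs of at least 5 neighbouring genes with at most 9 counts each, and the longest other run held 15 genes. DNA missing from this line or too diverged from the reference, and silence of these genes at the stages sampled, cannot be told apart, since there are no DNA reads here and the runs were chosen for their lack of reads.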

How the results depend on the processing

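The alternatives that kept every transcript line, used only spans that are multiples of 3, or left out genes with a missing fraction were chosen after the data were seen; all others were planned. With 1 library per group, no replicate could be left out. No paired analysis was possible because each group held 1 library. The order of the fractions kept its direction and its side of the threshold under 5 alternatives, with rho from -0.994 to -0.976 and r from -0.975 to -0.945. In all, 178 values that answer a comparison stayed within their limits and 103 moved. Median residuals within those limits still changed sign for merozoite invasion genes (-0.04 with a lowess span of 0.6) and glycolysis (-0.00188 with the median of the 100 nearest genes), and scaling turned the balance of higher and lower genes in fractions 1, 6, 7 and 8. The cause was not tested except where the alternative's own construction (fewer genes or counts, a wider or narrower threshold) gives it. Of the values of single genes, 103 stayed and 7 lost their call: with weights from the rebuilt library the residuals of H2A.Z, MSP2, RH1, HRP2 and RPB1, and with TMM the ratios of PF3D7_0821000 in fraction 3 (2.29) and PF3D7_0715300 in fraction 4 (2.42). Transcript or coding length and product-word lists were not run for want of a table, and a total with lines that name no gene was not run because there were none.

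With the 50 most abundant genes in place of 10, their share of counts was 21.9% in the unfractionated library, and 25.9%, 25.95%, 25.1%, 24.6%, 23.4%, 24.1%, 23.9% and 23.1% in fractions 1 to 8. The rho of centroid with span was -0.799 with weights from the rebuilt library, -0.702 with no minimum count, -0.806 with at least 500 counts, -0.835 with the fraction of highest CPM, -0.658 without fraction 1, -0.798 without fraction 7 and -0.804 without fraction 8. Those weights gave median centroids of 3.34 for chaperones and 3.48 for merozoite invasion genes.

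Genes higher in fractions 1 to 8 with the point ratio alone numbered 826, 470, 219, 164, 178, 366, 501 and 592, and genes lower 1385, 1045, 489, 325, 744, 1135, 1266 and 1265. Beyond 4-fold, genes higher numbered 0 in each of fractions 1 to 5 and 4, 2 and 2 in fractions 6, 7 and 8, and genes lower 44, 22, 7, 0, 19, 34, 77 and 97. With TMM, genes higher numbered 671, 116, 4, 0, 19, 400, 533 and 662, and genes lower 319 in fraction 1, 111 in fraction 4, and 144, 195 and 211 in fractions 6 to 8. With DESeq2, genes higher numbered 758 and 90 in fractions 1 and 2, 29 in fraction 5, and 399, 526 and 600 in fractions 6 to 8, and genes lower 244 in fraction 1 and 144, 197 and 252 in fractions 6 to 8. With upper quartiles, genes higher numbered 84 in fraction 2, 29 in fraction 5, and 310, 413 and 487 in fractions 6 to 8, and genes lower 202, 271 and 336 in fractions 6 to 8. With at least 50 counts, and when thinned, 4 genes were higher in fraction 3, and when thinned 31 were lower in fraction 4.

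Genes with smaller RNA numbered 121 of 2435 with at least 500 counts, 95 of 3850 with the weights and 114 of 2473 with spans that are multiples of 3, and genes with larger RNA 70, 42 and 53; of the 95 and 42, 94 and 42 were shared with the main calls. Genes with 2 maxima numbered 247 with a valley of up to 2/3 and 233 with at least 100 counts. The rebuilt library had an R2 of 0.973 with equal weights, 0.983 with no minimum and 0.982 with at least 50 counts, with 146 and 2 genes beyond 2-fold in these last 2. The median correlation of neighbouring fractions, that of fractions 1 and 8, and that of fractions 7 and 8 were 0.973, 0.790 and 0.985 with Spearman's rho and 0.975, 0.750 and 0.992 with log2(CPM + 10). Not all smaller changes were called in simulated data, where changed genes had at least 100 counts in the pair. The share of 3-fold changes called, among 50 changed genes per fraction, lay between 78.0% and 92.0%. The lowest were fractions 2 (4289 genes compared) and 6 (4239), and the highest was fraction 4 (4348). In fraction 7, the shallowest, the share was 80.0%, and 50 genes are too few to relate it to depth.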

Other observations

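The centroids and ratios are planned measures, whereas the genes set side by side, the comparison of fractions 7 and 8 by span and the search for missing fractions were chosen after the data were seen.

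Among the 8 histones, 3 variants lay apart from the other members in the gel. H4 (0.312 kb) centred on fraction 6.39, H3 on 6.38, H2A on 6.34 and H2B on 6.08, with counting standard errors of 0.01. H3.3, the replacement variant of H3 with the same span of 0.411 kb, centred on 5.56 ± 0.03, and H2B.Z on 5.01 ± 0.02, whereas H2A.Z, with a span of 1.08 kb, centred on 6.04 ± 0.01. CENH3, the centromeric variant, centred on 4.09 ± 0.06. H3 and H3.3 encode near-identical proteins, so reads shared between them would bring their values closer.

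The plasmepsins, haemoglobin proteases encoded side by side with spans near 1.36 kb, also differed in position. PMI centred on 2.75 ± 0.07, PMIV on 4.30 ± 0.05, HAP on 4.49 ± 0.04 and PMII on 5.07 ± 0.05. In fraction 8, PMI was at 0.04-fold of the unfractionated library (95% interval 0.01 to 0.11). The paired genes of cytoadherence-linked proteins differed as well, with CLAG3.2 (5.278 kb) on 2.49 ± 0.04 and CLAG3.1 (5.243 kb) on 3.49 ± 0.06. Reads shared between such copies leave these values uncertain.

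The log2 ratio of fraction 7 to fraction 8 was unrelated to span below 2 kb, with Spearman's rho of 0.0190 (95% bootstrap interval -0.0452 to 0.0920) across 778 genes under 1 kb and 0.0158 across 924 genes of 1 to 2 kb. It rose with span across 1226 genes over 2 kb (rho = 0.124, 0.0692 to 0.177). In 4 genes a fraction held at most 10% of what its neighbours gave, such as PF3D7_0321900 with 0 counts in fraction 3 beside 552 in fraction 2 and 236 in fraction 4.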
